A study of Mus musculus with 12 samples.

How the data were processed

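RNA from mouse yolk sacs was measured on 12 Agilent 2-colour arrays: 3 biological replicates each of wild type and of homozygotes for an Arid1a point mutation, at E8.5 and at E9.5. Per the labels, RNA was extracted with an organic reagent and spin columns with DNase on the column, a small amount was amplified and labelled with a low-input kit, yolk sac RNA carried Cy5, and a common reference RNA of whole neonatal mice carried Cy3 on every array. Dyes were not swapped. Per the file headers, the 12 arrays lay on 3 slides, each with 1 array of each of the 4 groups at a position fixed by the group, and were extracted with Agilent Feature Extraction 9.5.1.1.

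The deposited per-array files hold, for each spot, the mean intensity and the median local background intensity of each channel, without normalization. They also hold processed intensity values that the authors obtained from Feature Extraction, background-subtracted, spatially detrended and dye-normalized by LOWESS within each array. A further column holds, per the file headers, the log10 ratio of processed Cy5 over processed Cy3. The other columns used are flags of 0 or 1, per the file headers, for spots well above background, saturated or not uniform. The deposited table of all arrays holds log2 ratios centred by the authors on the median of each probe over the arrays. It keeps 19033 entries, of which 19007 are probes for transcripts and 26 are controls, and the filter behind it is not given in the sources used here. Its values correlated with the centred log ratios of the per-array files with r = 1 on every array.

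The arrays had 45018 spots, of which 1639 were controls, and 41174 distinct probes. Probe names were updated from a table of mouse gene names, by accession for 23374 probes, by current symbol for 6733 and by an older symbol for 2919. The other 8148 kept the name in the files or their probe identifier. In R 4.3.3 with the packages limma (version 3.58.1) and data.table (version 1.17.8), local background was removed with normexp and an offset of 50, and log2 ratios of Cy5 over Cy3 were normalized within each array by loess, with control spots at weight 0. Spots that Feature Extraction marked as outliers were set to missing, and repeated spots of a probe were averaged. Spots whose signal lay over 20 units below the local background were also set to missing, since normexp failed on mutant E9.5 replicate 3 from spots beside a bright speck. This rule was chosen after that failure was seen. A probe was kept if its Cy5 signal was well above background on all 3 arrays of at least 1 group (20064 probes), and each gene was represented by its probe with the highest mean intensity, which left 13895 genes, 11968 with an official symbol. Of these genes 176 had a Cy3 signal that was not well above background on any array. Values were missing 30 times.

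Limma was fitted to the 12 arrays with a mean for each of the 4 groups (8 residual and 6.23 prior degrees of freedom). The 5 contrasts were mutant minus wild type at E8.5 and at E9.5, their difference (the interaction), and E9.5 minus E8.5 in the wild type and in the mutant. In each, p-values were adjusted by Benjamini-Hochberg over all genes tested. An adjusted p under 0.05 counted as a change. Errors are standard errors of the fit unless given as SD. A signed difference on a slide compares the arrays of that slide.

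Gene lists written from general knowledge of the tissue were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry. A list needed 5 measured members, with Benjamini-Hochberg adjustment over the lists. The lists numbered 29. Of the yolk sac's own tissues they covered secreted proteins and transcription factors of visceral endoderm, apolipoproteins and lipid transport, endocytic and lysosomal machinery of visceral endoderm, and parietal endoderm. For blood and vessels they covered globins, other erythroid genes, early haematopoietic, megakaryocyte and myeloid genes, endothelial genes, and Notch pathway, arterial and venous genes. Connective tissue had mesenchyme, mesothelium and smooth muscle, and extracellular matrix and adhesion. Neighbouring tissues had trophoblast and placenta, decidua and maternal leukocytes, and neural, heart and muscle, and somite, limb and allantois markers of the embryo proper. Processes had SWI/SNF subunits, p53 targets, cell cycle and DNA replication, hypoxia and glycolysis, the Wnt and the TGF-beta and BMP pathways, cholesterol biosynthesis, imprinted and sex-linked genes. Responses had interferon-stimulated, immediate early, unfolded protein and amino acid stress, and heat shock genes.

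The contrasts, lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. Named were the 10 genes with the largest rise and the 10 with the largest fall in each contrast among official symbols that passed the threshold and whose groups did not overlap (this last was not asked for the interaction), filled to 5 by the smallest p where fewer passed. For a gene whose groups did not overlap, the same sign on every slide follows from that and adds no support. Arid1a was always named, and up to 4 members of each list with the smallest p. Genes of the tissue description, the neighbours of Arid1a and 2-fold changes were chosen after their values were seen.

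The steps were tested on simulated data of the same size, with 50 genes changed at each of 4 sizes on top of noise of the measured spread. At a log2 change of 0.5, 94% of the changed genes were recovered at E8.5, 96% at E9.5, 66% for the interaction and 90% for each stage contrast; at 0.25 the shares were 24%, 36%, 12%, 34% and 38%. Between 4 and 12 unchanged genes were called per contrast. The median standard error of a difference was 0.0674, and 0.0953 for the interaction.

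Alternatives to the values were no background subtraction, the processed signals, median centring in place of loess, Cy5 alone with quantile normalization, scale normalization between arrays, and the deposited table. Alternatives to the genes were no filter, both channels well above background on all arrays, every probe singly, and the mean of the kept probes. Alternatives to the fit were the 2 compared groups alone, the replicate number or the slide as a block, array weights, a trended robust prior, and leaving out each array in turn. Other thresholds were a log2 fold change of at least 1 and an adjusted p under 0.1. Chosen after seeing the data were the speck left in, an offset of 10, the Xist level as a covariate, a fit without the 4 arrays that had high trophoblast or embryo transcripts, the replicate number as a block within each genotype, and the slide as a block for the lists. Intensities of control spots, saturated spots and scanner settings were not analysed here.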

Results

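Gene expression was measured in the mouse yolk sac, the extraembryonic membrane in which the first blood cells form, at embryonic day 8.5 (E8.5) and at E9.5. The yolk sacs were wild type or homozygous for a point mutation in Arid1a (also called Baf250a), which encodes a DNA-binding subunit of the SWI/SNF chromatin-remodelling complex. Each of the 4 groups held 3 biological replicates, 1 per array, and the labels do not say whether a replicate was a single yolk sac or a pool. On each array, yolk sac RNA in Cy5 was hybridized against a common reference RNA from neonatal mice in Cy3. Between 47.4% (wild-type E8.5 replicate 2) and 50.7% (wild-type E9.5 replicate 3) of the probes were well above background in Cy5. The median Cy5 signal of an array lay between 43.1 and 46.8 intensity units, against median local backgrounds of 35 to 37. The number of arrays limits the precision, and the median standard error of a difference between groups was 0.0674 on the log2 scale. The 3 slides held 1 array of each group, with the position on the slide fixed by the group, so position and group cannot be told apart.

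Transcripts of neighbouring tissues were unevenly spread over the arrays. Prl4a1, a prolactin-family hormone gene of the trophoblast, had log2 ratios of 5.69, 4.31 and 3.74 in mutant E8.5 replicate 3, wild-type E9.5 replicate 3 and mutant E9.5 replicate 3, and between 0.26 and 1.53 in the other 9 arrays. Myl7, an atrial myosin light chain of the embryonic heart, stood at 0.01 in wild-type E8.5 replicate 2 and between -3.14 and -1.47 elsewhere. The same array had the highest Hes5, a Notch target of neural progenitors, at 0.06. Xist, the transcript that coats the inactive X chromosome of female cells, was at -4.01, -4.18 and -4.03 in mutant E8.5 replicates 2 and 3 and wild-type E9.5 replicate 2, and between -1.98 and -0.52 in the others. Y-linked Ddx3y stood at 0.48, 0.37 and 0.44 in those 3 arrays and between -0.46 and 0.15 in the others.

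The comparison at E8.5 asks which transcripts differed between Arid1a-mutant and wild-type yolk sacs while primitive blood and the first vessels form. Pf4, the platelet chemokine made by megakaryocytes, rose by 1.26 ± 0.12 on the log2 scale (SE, 3 arrays against 3; limma adjusted p = 0.000132) and was higher in the mutant on all 3 slides. Col1a1 and Col3a1, collagen chains of connective tissue, rose by 0.77 ± 0.11 and 0.61 ± 0.08. Csf2rb and Csf2rb2, receptor subunits through which myeloid cytokines signal, fell by 1.18 ± 0.13 and 1.09 ± 0.12, and Emid1 fell by 1.29 ± 0.09 (adjusted p = 7.48e-06). Rpl11, a protein of the large ribosomal subunit, fell by 0.81 ± 0.06. The other named genes that rose were Ifi27l2b, Mbl2, Tmem145, Rbm6, Exoc3l4, Ccdc68, Enpep and Rcc2, by 0.63 to 0.81, among them Mbl2, a lectin that starts the complement cascade, and Enpep, a membrane aminopeptidase. Those that fell were Hspa1a, Pop4, Slc51a, Krt7, Dynlt1b and Ambp, among them Krt7, a keratin of simple epithelia, and Ambp, the precursor of a plasma protease inhibitor.

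Hspa1a, the inducible Hsp70 chaperone, fell by 2.00 ± 0.43 (adjusted p = 0.0341; lower on 3 of 3 slides), with wild-type values at 0.66, -1.01 and 1.09. Its call was lost without wild-type E8.5 replicate 1 (-1.79) or 3 (-1.58), mutant E8.5 replicate 1 (-2.20), 2 (-1.88) or 3 (-1.92), wild-type E9.5 replicate 1 or mutant E9.5 replicate 2 (-2.00 in both cases). Among genes with another measured probe, that probe gave -1.86 for Hspa1a, -0.34 for Rpl11, -0.39 for Pop4, 0.30 and 0.08 for Col1a1, and 0.01 and 0.009 for Csf2rb and Rcc2. The other probe of Csf2rb and the second of Col1a1 were dim (mean log2 intensity 6.08 and 6.19, against 7.44 for the median gene), where a change is compressed. That of Rcc2 was not (9.54). In all, 31 of the 69 genes that changed and had several probes (44.9%) had another probe moving the same way by at least 50% as much. Arid1a itself differed by 0.05 ± 0.06 (adjusted p = 0.825), higher in the mutant on 3 of 3 slides and at -0.08 with median centring. A point mutation need not alter the transcript level, so this is no check of the labels.

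Blood gene lists had higher means in the E8.5 mutant. For the erythroid genes and globins this lay mostly in replicates 2 and 3, which were also the mutant arrays with low Xist. The erythroid genes lay 0.27 above their mean over all arrays in both, and 0.04 (replicate 1) above it in the other. Of 35 erythroid genes other than globins, 33 lay above 0 (mean 0.21; camera adjusted p = 5.22e-08), although 0 passed the limma test singly and 5 rose when adjusted over the list alone. The call was lost in camera (adjusted p = 0.774 with an estimated correlation) and was not made by fry (adjusted p = 0.446). It held with the processed signals, with median centring and with the mean of the kept probes. The erythroid mean differed between slides, at 0.002, 0.37 and 0.27. All 6 globin entries lay above 0 (mean 0.35, slide means 0.03, 0.54 and 0.48; camera adjusted p = 0.00143; adjusted p = 0.774 with an estimated correlation). Of these 1 rose, Eraf, the chaperone of free alpha globin, by 0.63 ± 0.14, against 2 adjusted over the list alone. Among 24 early haematopoietic, megakaryocyte and myeloid genes 3 rose and 0 fell (6 rose adjusted over the list alone), among them Pf4 and Treml1, a receptor of platelet granules, by 0.44 ± 0.08. The list mean was 0.14 (camera adjusted p = 0.00143; adjusted p = 0.774 with an estimated correlation). That list's mean was above 0 on 3 of 3 slides, at 0.11, 0.16 and 0.14. With the Xist level as a covariate the erythroid, globin and early haematopoietic means were 0.05, 0.12 and 0.07, and camera called none of them. Median centring gave 0.12, 0.22 and 0.06. Over 21 alternatives the early haematopoietic mean ranged from 0.057 to 0.295.

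Heat shock genes were lower in the E8.5 mutant. Of 17 measured members 4 fell and 0 rose (6 fell adjusted over the list alone): Hspa1a, Dnajb1 by 0.54 ± 0.12, Hspb8 by 0.43 ± 0.08 and Bag3 by 0.31 ± 0.07, all chaperones or co-chaperones. The list's mean was -0.30 (camera adjusted p = 9.81e-06; adjusted p = 0.218 with an estimated correlation). It was negative on 3 of 3 slides, and this was the 1 list called by fry (adjusted p = 0.0318). Fry tests whether the members move, on balance, in 1 direction, and does not compare them with other genes. The heat shock list lay 0.24 and 0.30 above its mean over all arrays in wild-type E8.5 replicates 1 and 3. On every other array, wild-type E8.5 replicate 2 (0.05) included, it lay between -0.15 and 0.10. The E8.5 mutant arrays, at -0.11 to -0.09, were near those of the E9.5 wild type, at -0.15 to -0.01. The endocytic and lysosomal genes of the visceral endoderm had a mean of 0.10, or -0.03 with median centring (camera adjusted p = 0.0178; adjusted p = 0.868 with an estimated correlation). Of its 21 genes 2 rose, the protease gene Ctsb by 0.32 ± 0.07 and the myosin gene Myo7a by 0.24 ± 0.05, against 3 risen and 2 fallen adjusted over the list alone. The hypoxia and glycolysis genes had a mean of -0.07 (camera adjusted p = 0.0206; adjusted p = 0.868 with an estimated correlation). Of these 1 of 34 fell, the phosphofructokinase gene Pfkp, by 0.29 ± 0.06, and 1 fell adjusted over the list alone. Interferon-stimulated genes had a mean of 0.08, or -0.006 with median centring (camera adjusted p = 0.0296; adjusted p = 0.774 with an estimated correlation). It was above 0 on 3 of 3 slides, with 0 of 23 called and 2 risen adjusted over the list alone. The endocytic call was lost with median centring and with the processed signals (0.09). The hypoxia call was lost with the processed signals (-0.05) and with the Xist covariate (-0.05), and its mean was -0.18 with median centring. With the Xist covariate the interferon call (0.06) was lost as well, and the interferon mean was 0.44 with the processed signals. Without 1 array, the interferon call was lost for wild-type replicate 1 (0.06) and mutant replicates 2 (0.07) and 3 (0.07). The endocytic and hypoxia calls were lost for wild-type replicate 2 (0.05 and -0.006) and mutant replicate 1 (0.09 and -0.05).

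Single members changed in lists that camera did not call at E8.5. In the visceral endoderm list F2 (prothrombin) rose by 0.48 ± 0.06 and Sox17, an endoderm transcription factor, by 0.39 ± 0.08, 2 of 26 members (4 risen and 2 fallen adjusted over the list alone). In the mesenchyme, mesothelium and smooth muscle list Col3a1, Col1a1 and Pdgfra rose, 3 of 30 (6 adjusted over the list alone). Sox7 and Cldn5, an endothelial transcription factor and tight-junction gene, rose by 0.28 ± 0.06 and 0.24 ± 0.05. Lyve1 fell by 0.37 ± 0.08 among the same 39 endothelial genes, with the same counts adjusted over the list alone. Sparc rose by 0.33 ± 0.06, the 1 member called of both the 33 extracellular matrix and adhesion genes (2 risen, 1 fallen adjusted over the list alone) and the 14 parietal endoderm markers (1 adjusted over the list alone). Cdx2, a caudal-type transcription factor, fell by 0.42 ± 0.07 among 10 trophoblast and placenta markers (1 risen, 1 fallen adjusted over the list alone). Of these 10 markers 9 lay above 0 with a mean of 0.44 and slide means of -0.05, 0.003 and 1.37, the last from the slide of the mutant array high in Prl4a1. Camera did not call them (adjusted p = 0.2; adjusted p = 0.868 with an estimated correlation), but did with the slide as a block (adjusted p = 0.0177). The same block gave a call of the heart and muscle markers (mean -0.15; adjusted p = 0.047), lower on 2 of 3 slides. Herpud1 fell by 0.32 ± 0.07 among 27 unfolded protein and amino acid stress genes, and Dlk1 rose by 0.34 ± 0.08 among 22 imprinted genes. Adjusted over the list alone, 1 fell in the first list, and 1 rose and 1 fell in the second. Adjusted over the list alone, 3 of the 20 apolipoprotein and lipid transport genes rose and 1 fell, 1 of 20 immediate early genes rose, and 2 of 5 sex-linked markers rose and 2 fell, with 0 called over all genes. The remaining lists had 0 members called in either way: Notch pathway, arterial and venous genes (19), decidua and maternal leukocyte markers (12), the neural (7) and heart and muscle (18) markers of the embryo proper, SWI/SNF subunits (26), p53 targets (24), cell cycle and DNA replication (40), Wnt (24), TGF-beta and BMP (30) and cholesterol biosynthesis (25). Only 4 of the somite, limb and allantois markers were measured, too few to test, and 0 of them were called. Median, mean and the direction of the camera test were not all of 1 sign for the mesenchyme list (median -0.01, mean 0.07), the sex-linked markers (median 0.13, mean -0.24) and, with means within 0.01 of 0, the Notch, cell cycle, TGF-beta, unfolded protein and imprinted lists.

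In total 98 genes rose and 103 fell at E8.5, 201 of 13895 tested, of which 6 changed at least 2-fold and all 201 had the same sign on the 3 slides. That sign was fixed, since in all 201 the arrays of the groups did not overlap, and it adds no support. The median size of these changes was 0.38 (log2). This size and the count of 2-fold changes understate dim genes, whose changes the offset compresses. At an unadjusted p under 0.05 there were 1721 genes, and the arrays of the groups did not overlap in 2498 genes, where chance alone gives 10%. With the slide as a block the count was 293. The count moved by over 1.5 times without wild-type E8.5 replicate 1 (128) or 3 (112) or mutant E8.5 replicate 1 (112), 2 (91) or 3 (104). Of the 40 named genes called, 23 lost their call without at least 1 of the 12 arrays, Myo7a without 11, Ctsb and Dlk1 without 10, Lyve1 and Pdgfra without 9, and Krt7 (-1.01 to -0.70) without 4. The count was 10 with median centring, 123 from the E8.5 arrays alone, 423 with array weights and 25 with the Xist covariate.

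At E9.5, the comparison asks the same of mutant and wild-type yolk sacs once the circulation has begun. The interferon-stimulated genes were higher as a group: 8 of 23 rose and 0 fell (12 rose adjusted over the list alone), and 22 lay above 0. Rtp4, an interferon-induced chaperone of receptors, rose by 0.68 ± 0.10 (SE, 3 arrays against 3; limma adjusted p = 0.00134), the antiviral enzyme genes Oasl2 and Oas1a by 0.56 ± 0.09 and 0.41 ± 0.06, and Isg15, a ubiquitin-like modifier, by 0.49 ± 0.08. Cpb2, a carboxypeptidase that slows the breakdown of fibrin, rose by 0.88 ± 0.06 (adjusted p = 4.22e-06), and its other probe gave 0.74. Emid1, Csf2rb and Csf2rb2 fell by 1.13 ± 0.09, 1.06 ± 0.13 and 0.89 ± 0.12, and Rpl11 by 0.88 ± 0.06. Pik3cd, the leukocyte form of phosphoinositide 3-kinase, fell by 0.98 ± 0.08 and Sirpa, an inhibitory receptor of myeloid cells, by 0.82 ± 0.15.

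Exoc3l4, Enpep, Esm1, Tmem145, Ifi27l2b, Slc22a6, Plac8 and Slc5a4b also rose at E9.5, by 0.66 to 0.92, among them Esm1, a proteoglycan secreted by endothelium, and Slc22a6, a transporter of organic anions. Pi4k2b, Serpinb1a, Tulp2 and Ambp fell, by 0.81 to 0.86, among them Serpinb1a, an inhibitor of leukocyte proteases. The Pi4k2b call (adjusted p = 0.0461) was lost without any array except mutant E9.5 replicate 2 and wild-type E8.5 replicate 2, with values from -0.91 to -0.53, the weakest without mutant E9.5 replicate 1. The other probes of Csf2rb and Rpl11, both dimmer than the median gene, gave 0.03 and -0.16, and 45 of the 87 changed genes with several probes (51.7%) had another probe moving the same way by at least 50% as much. Arid1a was 0.16 ± 0.06 higher (adjusted p = 0.3), on 3 of 3 slides.

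The interferon list had a mean of 0.25 at E9.5 (camera adjusted p = 1.61e-14). It was called with an estimated correlation as well (adjusted p = 0.0484 with an estimated correlation) and by fry (adjusted p = 0.0037), the 1 list of this comparison with either call. Its mean was 0.15, 0.26 and 0.33 on the 3 slides, and over all slides 0.68 with the processed signals. Other splits of the E9.5 arrays gave up to 11 lists called with the preset correlation, against the real 4. Of 30 TGF-beta and BMP pathway genes 3 rose and 0 fell (5 rose adjusted over the list alone): Id3, an inhibitor of helix-loop-helix factors, by 0.46 ± 0.08, and the secreted matrix proteins Tgfbi and Ccn2 by 0.48 ± 0.09 and 0.50 ± 0.10. Id3 lies within 100 tested genes of Arid1a on chromosome 4, so the limits given below for those neighbours apply to it. The list mean was 0.09, above 0 on 3 of 3 slides (camera adjusted p = 0.0193; adjusted p = 0.994 with an estimated correlation). Of 20 apolipoprotein and lipid transport genes the fatty-acid-binding protein genes Fabp1 and Fabp2 rose, by 0.46 ± 0.08 and 0.34 ± 0.08 (3 rose adjusted over the list alone; list mean 0.08, above 0 on 2 of 3 slides; camera adjusted p = 0.0291; adjusted p = 0.994 with an estimated correlation). The erythroid genes other than globins had a mean of 0.09 with 28 of 35 above 0 and 0 called, also 0 adjusted over the list alone (camera adjusted p = 0.0333; adjusted p = 0.994 with an estimated correlation). Their slide means were 0.33, 0.01 and -0.08, and without mutant E9.5 replicate 1 the mean was -0.04. That was the lowest of 21 alternatives, and the highest was 0.183. Median centring gave 0.04 for the TGF-beta, 0.01 for the apolipoprotein and 0.03 for the erythroid mean. All 3 calls were lost with the processed signals, at 0.16, 0.12 and 0.11. The erythroid call was also lost without wild-type replicate 1 (0.09), 2 (0.09) or 3 (0.08), and the TGF-beta call without wild-type replicate 1 (0.07) or mutant replicate 1 (0.08). Camera lost the apolipoprotein call without wild-type replicate 1 (0.06) or 3 (0.06) or mutant replicate 2 (0.03) or 3 (0.06). The array with the highest erythroid level of the E9.5 mutant, replicate 1, was not among those high in Prl4a1.

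Outside the lists that camera called at E9.5, Mpo, the peroxidase of neutrophil granules, fell by 0.62 ± 0.10 and Ppbp, a platelet chemokine, rose by 0.47 ± 0.09 among the 24 early haematopoietic, megakaryocyte and myeloid genes (2 risen, 2 fallen adjusted over the list alone). Unc5b, a netrin receptor of arteries, fell by 0.35 ± 0.08 among 19 Notch pathway, arterial and venous genes (2 fallen adjusted over the list alone). F2 rose by 0.47 ± 0.06 in the visceral endoderm list (2 adjusted over the list alone). Sparc and Lamb2 rose by 0.34 ± 0.06 and 0.27 ± 0.06 among the extracellular matrix and adhesion genes (3 risen, 1 fallen adjusted over the list alone). Sparc was the 1 called among the parietal endoderm markers (2 adjusted over the list alone). Cdx2 fell by 0.39 ± 0.07 (1 fallen among the trophoblast markers adjusted over the list alone). Peg10, a retrotransposon-derived placental gene, fell by 0.35 ± 0.08 (1 among the imprinted genes adjusted over the list alone). Pmaip1, a BH3-only inducer of apoptosis, rose by 0.46 ± 0.07 among the p53 targets (2 adjusted over the list alone). Dkk1, a secreted Wnt antagonist, rose by 0.53 ± 0.10 among the Wnt genes (1 risen, 1 fallen adjusted over the list alone). Adjusted over the list alone, 1 globin rose and 1 heart and muscle marker fell. The endocytic, endothelial, mesenchyme, decidua, neural, SWI/SNF, cell cycle, hypoxia, cholesterol, immediate early, unfolded protein, heat shock and sex-linked lists had 0 members called in either way. The 4 somite, limb and allantois markers had 0 called over all genes. Median, mean and the camera direction were not all of 1 sign for the heart and muscle markers (median 0.04, mean -0.04), the sex-linked markers (median -0.09, mean 0.15), the trophoblast markers (mean 0.03, camera direction down), the visceral endoderm list (median -0.002, mean 0.04) and, with means within 0.01 of 0, the early haematopoietic, mesenchyme, extracellular matrix and hypoxia lists.

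In total 124 genes rose and 150 fell at E9.5, 274 of 13895, of which 2 changed at least 2-fold and all 274 had the same sign on the 3 slides. Here too the groups did not overlap in all 274, so the sign was fixed and adds no support. The median size was 0.38 (log2), 1661 genes lay at an unadjusted p under 0.05, and the groups did not overlap in 2395 genes, where chance gives 10%. With the slide as a block the count was 361. The count moved by over 1.5 times without wild-type E9.5 replicate 1 (162) or 2 (145) or mutant E9.5 replicate 2 (168). Of the 38 named genes called, 9 lost their call without at least 1 array, among them Pi4k2b, Peg10 without 8 of 12, and Fabp2 without 5. The count was 26 with median centring, 170 from the processed signals, 181 from the deposited value table and 134 with the Xist covariate.

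The mutant effects of the stages overlapped. Of the genes called at E8.5 or E9.5, 87 were called at both, 34 higher and 53 lower at both and 0 in opposite directions, where independent calls would give 0.875 and 1.11. Among the 388 genes called at either stage 90.7% had the same sign at both. Emid1, Csf2rb, Csf2rb2, Rpl11 and Ambp were among those lower at both, and Enpep, Exoc3l4, Ifi27l2b and Tmem145 among those higher at both. Across all genes, which are not independent replicates, the effects correlated with Pearson's r = 0.396 and Spearman's rho = 0.326.

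**Figure D1:**
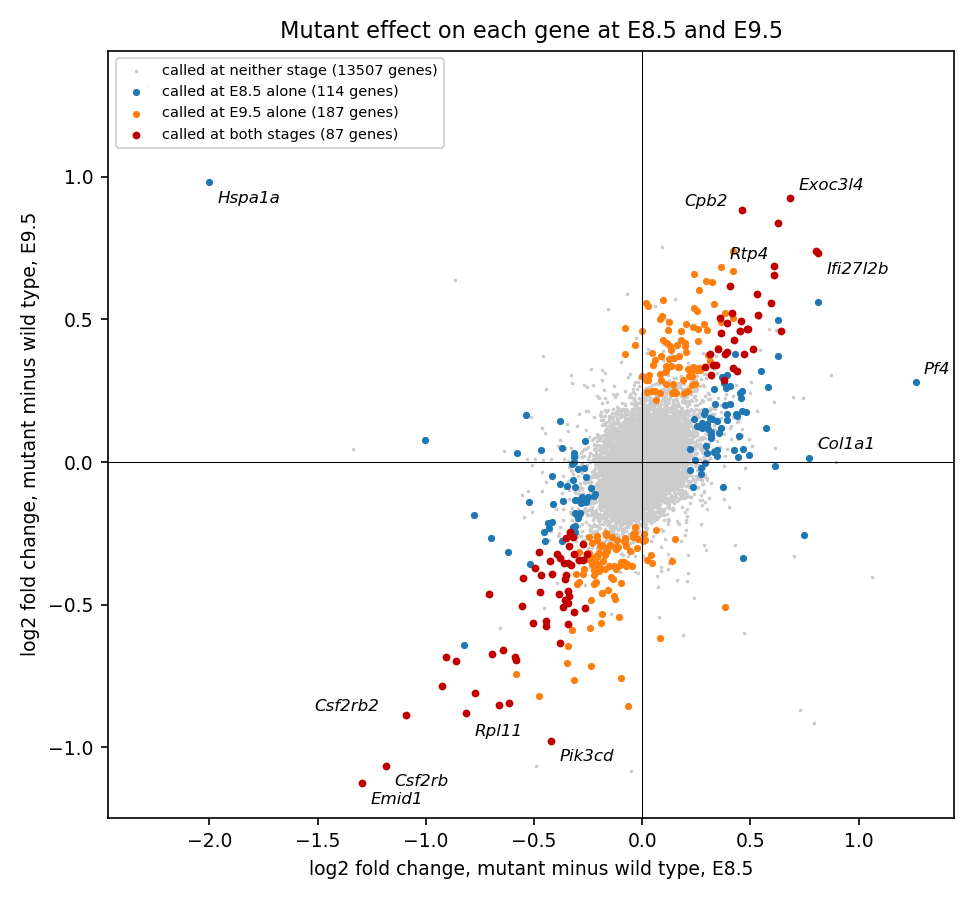
Each point is a gene, with the log2 fold change of mutant minus wild type at E8.5 on the horizontal axis and at E9.5 on the vertical axis (3 arrays per group); colours mark genes called by limma at neither stage, at E8.5 alone, at E9.5 alone or at both. The 87 genes called at both lie in the lower left and the upper right of the plot, and Pf4, at 1.26 and 0.28, and Hspa1a, at -2.00 and 0.98, lie off that diagonal.

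The interaction asks whether the mutant effect at E9.5 differed from that at E8.5. Limma called 0 genes, the smallest adjusted p being 0.113, with 800 genes at an unadjusted p under 0.05. Other forms of the limma fit called 1 gene with the slide as a block, 5 with array weights and 1 with a trended robust prior. Genes among those with the smallest p had a lower mutant effect at E9.5 for Plekhd1 (-0.66 ± 0.10; adjusted p = 0.113), Pf4 (-0.99 ± 0.17; 0.161), Rbm6, Col3a1 and Cwc22. A higher one was seen for Oas1a (0.44 ± 0.08; adjusted p = 0.161), Myh14, Cpb2 and Hspa1a (2.98 ± 0.61; 0.265). Each of these had the same sign on 3 of 3 slides. Plekhd1 was above background on 1 wild-type and 0 mutant arrays at E8.5, and Oas1a on 1 wild-type array at E8.5, so the E8.5 part of these values is uncertain. Arid1a differed by 0.11 ± 0.09 (adjusted p = 0.949). The count was 5 without wild-type E9.5 replicate 3, 1 without wild-type E8.5 replicate 2 or mutant E9.5 replicate 2, and 12 without the 4 arrays with high trophoblast or embryo transcripts.

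Camera called 7 lists for the interaction, of which 0 were called with an estimated correlation and 0 by fry. The interferon-stimulated genes (mean 0.17; camera adjusted p = 1.07e-07; adjusted p = 0.14 with an estimated correlation) and the heat shock genes (mean 0.40; camera adjusted p = 1.34e-06; adjusted p = 0.14 with an estimated correlation) had a higher mutant effect at E9.5 on 3 of 3 slides. Adjusted over the list alone 5 members of each were called, among them Oas1a, Oasl2, Hspa1a and Dnajb1. The heat shock difference draws on wild-type E8.5 replicates 1 and 3, the arrays highest in that list. The TGF-beta and BMP genes (mean 0.08; camera adjusted p = 0.0133; adjusted p = 0.719 with an estimated correlation; 1 called adjusted over the list alone, Id3, a neighbour of Arid1a on chromosome 4) were higher on 3 of 3 slides. The hypoxia and glycolysis genes were higher on 2 of 3 (mean 0.07; camera adjusted p = 0.0239; adjusted p = 0.87 with an estimated correlation; 0 adjusted over the list alone). The early haematopoietic, megakaryocyte and myeloid genes were lower (mean -0.14; camera adjusted p = 0.00109; adjusted p = 0.719 with an estimated correlation) on 3 of 3 slides, with 6 members lower, among them Pf4 and Mpo, and 1 higher, Ppbp, which was above background on 0 arrays of both groups at E8.5, adjusted over the list alone. Erythroid genes (mean -0.13; camera adjusted p = 0.0096; adjusted p = 0.87 with an estimated correlation) and globins (mean -0.23; camera adjusted p = 0.042; adjusted p = 0.812 with an estimated correlation) were lower as well. Their slide means were 0.33, -0.36 and -0.35, and 0.31, -0.46 and -0.53, with 0 called adjusted over either list alone. With the Xist covariate both means were 0.13, the opposite direction. Camera called the erythroid list in that direction (adjusted p = 0.0126) and did not call the globins (adjusted p = 0.469). Over all 21 alternatives, in either direction, the adjusted p of camera or fry ranged from 4.07e-14 to 0.873 for the erythroid list. For the globins it ranged from 0.000298 to 0.873. The early haematopoietic (-0.04), hypoxia (0.04) and TGF-beta (0.07) calls were lost with that covariate, while the interferon and heat shock calls were kept. With the processed signals the interferon (0.24), TGF-beta (0.13), hypoxia (0.03), erythroid (-0.16) and globin (-0.20) calls were lost, which left the heat shock and early haematopoietic calls. These calls rested on few arrays. The erythroid call was lost without wild-type E8.5 replicate 2 (-0.09), mutant E8.5 replicate 2 (-0.09) or 3 (-0.09), or mutant E9.5 replicate 2 (-0.09) or 3 (-0.04). The globin call was lost without wild-type E8.5 replicate 2 (-0.23) or 3 (-0.19), mutant E8.5 replicate 2 (-0.13) or 3 (-0.20), wild-type E9.5 replicate 1 (-0.22) or 2 (-0.20), or mutant E9.5 replicate 2 (-0.23) or 3 (-0.11). The TGF-beta call was lost without wild-type E8.5 replicate 2 (0.05) or mutant E9.5 replicate 1 (0.07). The hypoxia call was lost without wild-type E8.5 replicate 2 (0.005), mutant E8.5 replicate 1 (0.05), wild-type E9.5 replicate 1 (0.04) or 2 (0.06), or mutant E9.5 replicate 1 (0.07) or 2 (0.06). With the slide as a block camera also called the trophoblast (mean -0.41; adjusted p = 0.0169) and the heart and muscle markers (mean 0.12; adjusted p = 0.0479), each with that sign on 2 of 3 slides. Among lists that camera did not call, adjusted over the list alone, 1 endothelial gene was higher and 2 lower, among them Cldn5 (-0.32 ± 0.07). In the same way 3 Notch pathway, arterial and venous genes were lower, among them Unc5b (-0.49 ± 0.11), and 2 mesenchyme genes were lower, Col3a1 and Col1a1. Of the sex-linked markers 2 were higher and 3 lower adjusted over the list alone. The other lists had 0 members called in either way. Median, mean and camera direction were not all of 1 sign for the sex-linked markers (median -0.22, mean 0.39), the Wnt (median -0.02, mean 0.02) and endothelial genes (median 0.01, mean -0.03) and, with means within 0.01 of 0, the decidua, immediate early and cholesterol lists.

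**Figure D2:**
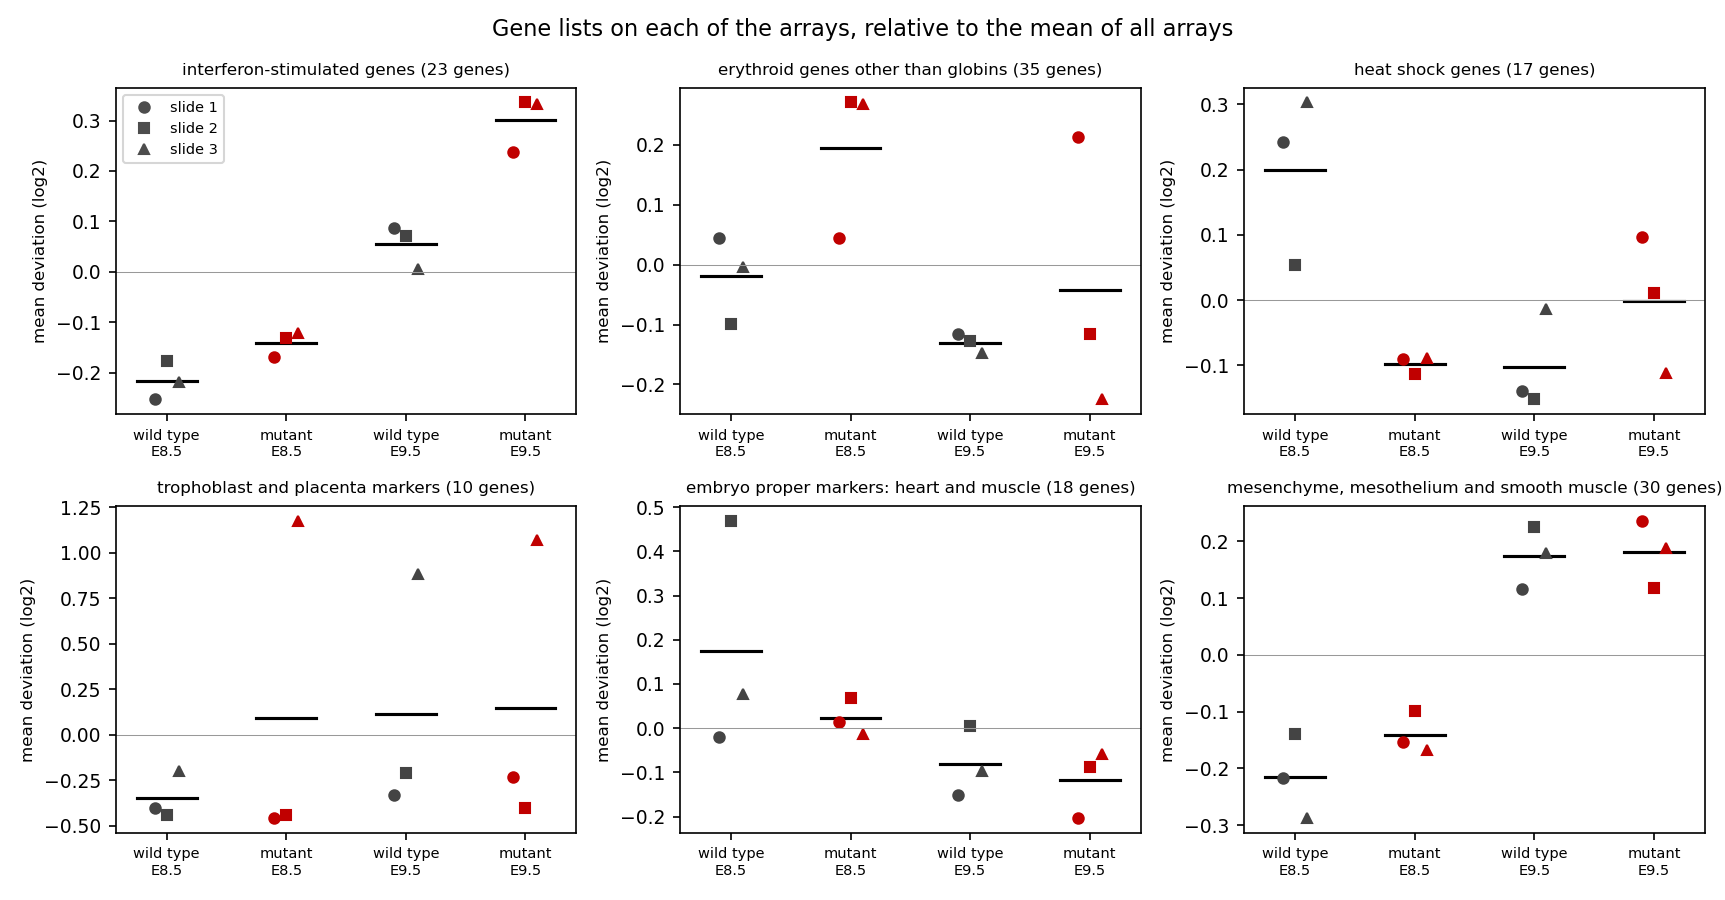
Each panel plots, for 1 gene list, the mean deviation of its measured members from their mean over all arrays (log2, vertical axis) on each of the 12 arrays, grouped by genotype and stage, with a bar at the group mean and symbols for the slides. The interferon-stimulated genes of the 3 E9.5 mutant arrays, between 0.24 and 0.34, lie above all others, the erythroid values of the E9.5 mutant spread from -0.23 to 0.21, and 3 arrays of slide 3 have trophoblast marker means of 1.18, 0.88 and 1.07.

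From E8.5 to E9.5 Pf4, Cfi, Afp and the type I collagen genes were among the largest rises in the wild-type yolk sac. This comparison asks how the tissue changed over a day. Pf4 rose by 2.19 ± 0.12 (log2; SE, 3 arrays against 3; limma adjusted p = 1.89e-07), Cfi, a protease that controls complement, by 1.92 ± 0.12, and Afp, the fetal plasma protein made by visceral endoderm, by 1.72 ± 0.11. Col1a1 and Col1a2, the chains of type I collagen, rose by 1.88 ± 0.11 and 1.60 ± 0.12, and Slc27a2, a fatty-acid transporter, by 1.69 ± 0.10. Cyp26a1, which degrades retinoic acid, fell by 1.31 ± 0.10, Dnmt3b, a de novo DNA methyltransferase, by 1.03 ± 0.10, and Apln, a peptide ligand of endothelial tip cells, by 1.15 ± 0.12. Urah, Akr1c19, Gsn and Serpind1 rose as well, by 1.56 to 1.68, and Cpne7, Amot, Prss12, Slco3a1, Hk2 and Hipk2 fell, by 1.00 to 1.66. Myl7 fell by 1.73 ± 0.39 (adjusted p = 0.00546; lower on 3 of 3 slides), with wild-type E8.5 replicate 2 at 0.01 beside -2.50 and -1.47 in replicates 1 and 3. Arid1a fell by 0.32 ± 0.06 (adjusted p = 0.00272), on 3 of 3 slides, a call that was lost with median centring (-0.15).

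In the mutant, the same comparison gave Slc27a2, Urah, Cfi, Serpind1, Afp and Gsn among the 10 largest rises, of up to 1.93, and Cpne7, Cyp26a1, Dnmt3b, Apln and Prss12 among the 10 largest falls. Krt7 rose by 1.58 ± 0.16 and Maob, a monoamine oxidase, by 1.74 ± 0.12 (limma adjusted p = 4.3e-07, higher on 3 of 3 slides). Zfpm1, the GATA1 cofactor FOG1, fell by 1.02 ± 0.13, Cd24a by 1.22 ± 0.17, Baz1a, an imitation-switch remodelling subunit, by 0.99 ± 0.08, and Prkar2b by 0.97 ± 0.09. Hspa1a rose by 1.52 ± 0.43 (adjusted p = 0.0212). Xist rose by 2.18 ± 0.63 (adjusted p = 0.0238) and Y-linked Eif2s3y fell by 1.00 ± 0.20, in the groups where 2 of the 3 E8.5 arrays and 0 of the E9.5 arrays had low Xist. Arid1a fell by 0.20 ± 0.06 (adjusted p = 0.0334; lower on 3 of 3 slides), a call that was lost without mutant E8.5 replicate 2 (-0.18) or 3 (-0.18) or mutant E9.5 replicate 1 (-0.16) or 3 (-0.22), and its value was 0.004 with median centring.

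**Figure D3:**
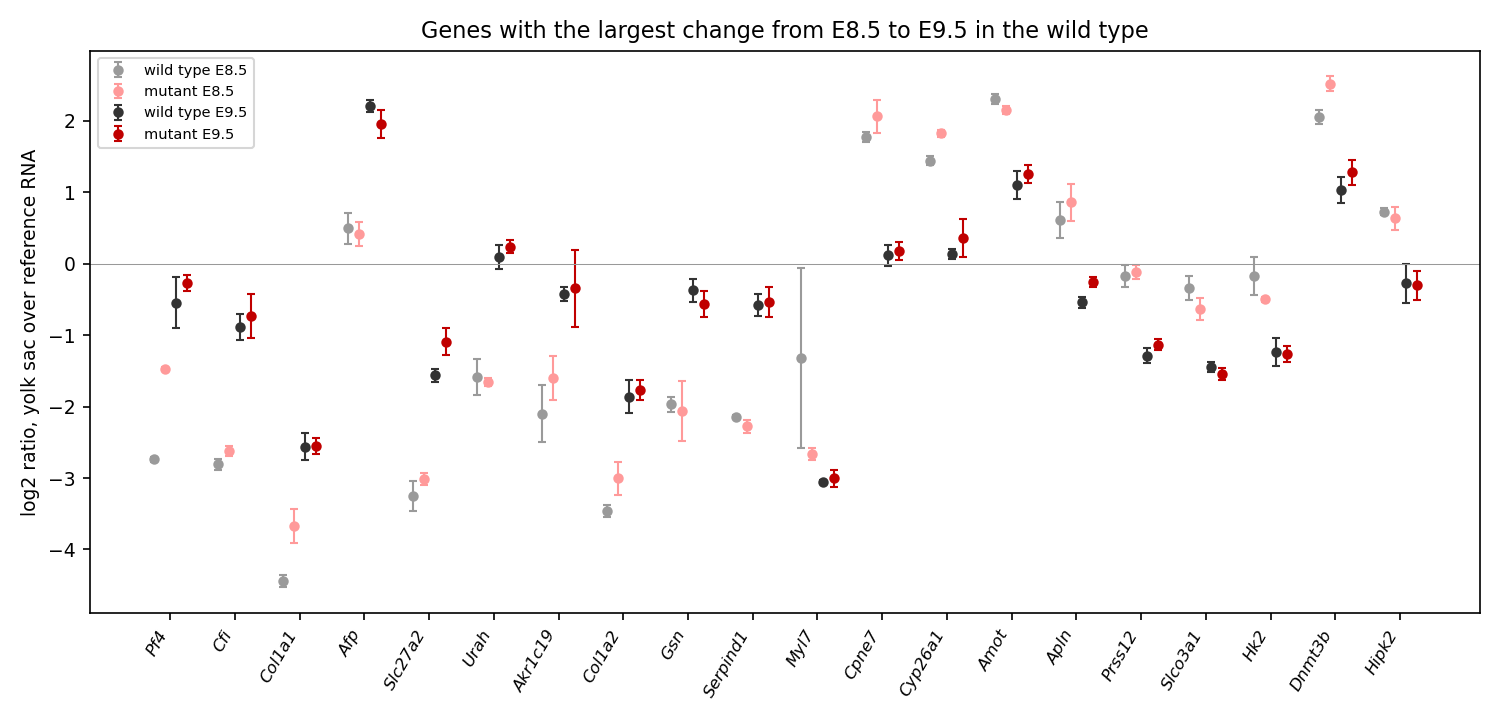
Points give the mean log2 ratio of yolk sac over reference RNA (vertical axis) in each of the 4 groups, with the SD of 3 arrays as bars, for the 10 genes that rose the most and the 10 that fell the most from E8.5 to E9.5 in the wild type. Dark symbols (E9.5) lie above light ones (E8.5) for Pf4 to Serpind1 and below them for Myl7 to Hipk2 in both genotypes, and Myl7 has its wide bar in the wild type at E8.5.

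The visceral endoderm, mesenchyme and extracellular matrix lists had higher means at E9.5 in both genotypes. For the visceral endoderm list 10 of 26 rose and 1 fell in the wild type (the same counts adjusted over the list alone), and 10 rose and 1 fell in the mutant (11 and 1 adjusted over the list alone). In it were Fga and Fgg, chains of fibrinogen, up by 0.97 and 0.92 in the wild type and 1.05 and 1.17 in the mutant. List means were 0.29 and 0.28 (camera adjusted p = 0.000409 and 0.000521; adjusted p = 0.279 and adjusted p = 0.299 with an estimated correlation). Of the mesenchyme list 12 of 30 rose and 0 fell in the wild type (15 and 1 adjusted over the list alone), and 11 rose and 2 fell in the mutant (12 and 2 adjusted over the list alone). Upk3b, a mesothelial plaque protein gene, was up by 1.16 and 1.07. List means were 0.39 and 0.33 (camera adjusted p = 0.000265 and 0.000128; adjusted p = 0.279 and adjusted p = 0.262 with an estimated correlation). Of the extracellular matrix and adhesion genes 17 of 33 rose in the wild type and 13 in the mutant, and 0 fell (18 and 15 rose adjusted over the list alone), among them fibronectin, Fn1, by 0.50 and 0.48. List means were 0.20 and 0.16 (camera adjusted p = 3.51e-05 and 9.05e-05; adjusted p = 0.279 and adjusted p = 0.299 with an estimated correlation). The slide means of these 3 lists were above 0 on 3 of 3 slides in both genotypes. Median centring gave 0.45 and 0.49 for the visceral endoderm, 0.55 and 0.52 for the mesenchyme and 0.36 and 0.37 for the matrix means.

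Interferon-stimulated genes rose in number as well: 10 of 23 in the wild type and 17 in the mutant, and 0 fell (11 and 19 adjusted over the list alone), led by B2m, the light chain of class I histocompatibility molecules, by 1.24 and 1.23. List means were 0.27 and 0.44, or 0.97 and 1.21 with the processed signals (camera adjusted p = 2.29e-05 and 4.38e-13; adjusted p = 0.228 and adjusted p = 0.0661 with an estimated correlation). Of the imprinted genes 11 of 22 rose and 2 fell in the wild type (12 and 2 adjusted over the list alone) and 9 rose and 1 fell in the mutant (10 and 1 adjusted over the list alone). Cdkn1c, a cyclin-dependent kinase inhibitor, was up by 0.89 and 0.82. List means were 0.26 and 0.25 (camera adjusted p = 0.00135 and 0.00178; adjusted p = 0.228 and adjusted p = 0.262 with an estimated correlation). Of the cholesterol biosynthesis genes 5 of 25 rose and 1 fell in the wild type (6 and 1 adjusted over the list alone) and 6 rose and 0 fell in the mutant (7 and 1 adjusted over the list alone). Fdft1, squalene synthase, was up by 0.50 and 0.35. List means were 0.10 and 0.11 (camera adjusted p = 0.0194 and 0.00492; adjusted p = 0.279 and adjusted p = 0.262 with an estimated correlation). Of the apolipoprotein and lipid transport genes 6 of 20 rose and 1 fell in the wild type (7 and 3 adjusted over the list alone) and 8 rose and 2 fell in the mutant (9 and 2 adjusted over the list alone). Apoa4 was up by 0.76 and 1.02. List means were 0.17 and 0.22 (camera adjusted p = 0.0305 and 0.00329; adjusted p = 0.593 and adjusted p = 0.499 with an estimated correlation). Of the endocytic and lysosomal genes 9 of 21 rose and 0 fell in the wild type (the same adjusted over the list alone) and 5 rose and 2 fell in the mutant (6 and 2 adjusted over the list alone). Fcgrt, the neonatal Fc receptor, was up by 0.78 and 0.96. List means were 0.17 and 0.10 (camera adjusted p = 0.00128 and 0.0379; adjusted p = 0.496 and adjusted p = 0.646 with an estimated correlation). Leaving out 1 array ended some of these calls. In the wild type the apolipoprotein call was lost without E8.5 replicate 2 (0.13) or E9.5 replicate 2 (0.13), and the cholesterol call without E8.5 replicate 1 (0.09) or E9.5 replicate 3 (0.08). In the mutant the endocytic call was lost without E8.5 replicate 3 (0.09) or E9.5 replicate 3 (0.06). Median centring gave endocytic means of 0.37 and 0.35, cholesterol means of 0.25 and 0.30, and apolipoprotein means of 0.34 and 0.44. The endocytic call in the mutant and the cholesterol call in the wild type were lost with it. With the Xist covariate the endocytic (0.07) and cholesterol (0.09) calls in the mutant and the apolipoprotein call (0.15) in the wild type were lost. The interferon and imprinted means were 0.40 and 0.61, and 0.45 and 0.48, with median centring.

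In the cell cycle and erythroid lists more genes fell than rose with stage, while most members were not called. The means of both lists changed sign with median centring, apart from the erythroid mean in the mutant. Of 40 cell cycle and DNA replication genes 11 fell and 1 rose in the wild type (17 and 1 adjusted over the list alone) and 14 fell and 0 rose in the mutant (17 and 3 adjusted over the list alone). The replication helicase gene Mcm3 fell by 0.39 and 0.46. List means were -0.13 and -0.14, or 0.03 and 0.07 with median centring (camera adjusted p = 0.000838 and 0.000133; adjusted p = 0.228 and adjusted p = 0.257 with an estimated correlation). Of 35 erythroid genes other than globins 9 fell and 2 rose in the wild type (10 and 2 adjusted over the list alone) and 13 fell and 2 rose in the mutant (the same adjusted over the list alone). Among them the transcription factor genes Gata1 changed by -0.36 and -0.49, and Klf1 by -0.54 and -0.83. List means were -0.11 and -0.24, or 0.02 and -0.06 with median centring (camera adjusted p = 0.0451 and 0.000439; adjusted p = 0.688 and adjusted p = 0.646 with an estimated correlation). The erythroid call in the wild type was lost without wild-type E8.5 replicate 1 (-0.08) or 3 (-0.10), wild-type E9.5 replicate 2 (-0.11) or 3 (-0.10), or mutant E8.5 replicate 2 (-0.11), and with the slide as a block (adjusted p = 0.0618; 0.000483 to 0.688 over 21 alternatives). It was also lost with the processed signals (-0.12). The erythroid call in the mutant was lost with the Xist covariate (-0.08). The erythroid slide means were -0.16, -0.03 and -0.14 in the wild type and 0.17, -0.39 and -0.49 in the mutant.

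Camera called 4 lists with stage in the wild type that it did not call in the mutant. Of the heat shock genes 10 of 17 fell and 1 rose (12 and 1 adjusted over the list alone). The list mean was -0.30 (camera adjusted p = 0.000838; adjusted p = 0.228 with an estimated correlation). Wild-type E8.5 replicates 1 and 3 were the arrays highest in this list, 0.24 and 0.30 above its mean over all arrays. In the mutant 6 fell and 4 rose (6 and 5 adjusted over the list alone; camera adjusted p = 0.837). Of the hypoxia and glycolysis genes 8 of 34 fell and 2 rose, Hk2 by -1.06 and Bnip3 by 0.45 (9 and 2 adjusted over the list alone). The list mean was -0.11, or 0.04 with median centring (camera adjusted p = 0.0414; adjusted p = 0.593 with an estimated correlation). Of the same list 5 fell and 2 rose in the mutant (6 and 4 adjusted over the list alone). Of the heart and muscle markers Myl7, Tnnt2, Tnnc1 and Myh6 fell, 4 of 18 (5 adjusted over the list alone). The list mean was -0.26 (camera adjusted p = 0.00953; adjusted p = 0.593 with an estimated correlation), with slide means of -0.13, -0.46 and -0.17, the second from the slide with the high Myl7. In the mutant 0 fell, also 0 adjusted over the list alone. Of the SWI/SNF subunits 5 of 26 fell in the wild type, among them Bcl7a, Arid1a and Phf10, and 4 in the mutant, and 0 rose (5 and 4 adjusted over the list alone). List means were -0.10, or 0.04 with median centring, and -0.08 (camera adjusted p = 0.027 and 0.165; adjusted p = 0.518 and adjusted p = 0.71 with an estimated correlation). The unfolded protein and amino acid stress genes were called in the mutant, 8 of 27 risen and 3 fallen (the same adjusted over the list alone), with Gpt2, an alanine aminotransferase, up by 0.69. The list mean was 0.11 (camera adjusted p = 0.013; adjusted p = 0.299 with an estimated correlation). In the wild type 6 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.168). Without wild-type E8.5 replicate 2 the heart (-0.11), SWI/SNF (-0.06) and hypoxia (-0.06) calls were lost. The SWI/SNF call was also lost without mutant E8.5 replicate 2 (-0.09) or wild-type E9.5 replicate 3 (-0.09), and the hypoxia call without mutant E8.5 replicate 2 (-0.11) or wild-type E9.5 replicate 1 (-0.09) or 2 (-0.11). The hypoxia call was also lost with the processed signals (-0.08) and the Xist covariate (-0.11), and with median centring the SWI/SNF call in the wild type and the unfolded protein call in the mutant (0.31) were lost. Median centring gave -0.14 for the heat shock and -0.10 for the heart mean in the wild type. A difference between the genotypes is tested by the interaction, in which camera called the heat shock and hypoxia lists with the preset correlation and neither with the estimated 1. It did not call the heart (adjusted p = 0.0894, or 0.0479 with the slide as a block), SWI/SNF (0.375) and unfolded protein (0.0795) lists, with means of 0.12, 0.02 and 0.05.

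Among lists not called with stage in either genotype, 9 of the early haematopoietic, megakaryocyte and myeloid genes rose and 4 fell in the wild type (10 and 4 adjusted over the list alone) and 6 rose and 5 fell in the mutant (6 and 6 adjusted over the list alone). Mpo was up by 0.94 in the first. Ppbp, above background on 0 of 3 mutant arrays at E8.5, was at least 1.9-fold higher at E9.5 in the second. Among the globins Hbb-y, the embryonic beta-like chain, rose by 0.98 and Hba-a1 by 0.52 in the wild type, 2 of 6, and 0 in the mutant (2 and 0 adjusted over the list alone). Of the endothelial genes 7 rose and 7 fell in the wild type (8 and 8 adjusted over the list alone) and 5 rose and 6 fell in the mutant (7 and 6 adjusted over the list alone). Of the Notch, arterial and venous genes 4 rose and 1 fell in the wild type (the same adjusted over the list alone), the arterial connexin gene Gja5 by 0.68, and 0 rose and 2 fell in the mutant (0 and 1 adjusted over the list alone). Of the TGF-beta and BMP genes 5 rose and 7 fell in the wild type (6 and 9 adjusted over the list alone) and 12 rose and 4 fell in the mutant (12 and 5 adjusted over the list alone). Of the p53 targets 5 rose and 1 fell in the wild type (the same adjusted over the list alone) and 6 rose and 1 fell in the mutant (9 and 1 adjusted over the list alone). Of the Wnt genes 2 rose and 2 fell, and 1 rose and 0 fell (2 and 2, and 0 and 0, adjusted over the list alone). Of the parietal endoderm markers 5 rose and 1 fell, and 3 rose and 1 fell (5 and 1, and 4 and 1, adjusted over the list alone). Of the decidua markers 3 rose in each genotype (4 and 3 adjusted over the list alone), Lum among them, which is also on the mesenchyme list. Of the trophoblast markers Rhox9 and Rhox6 rose in the wild type and Hand1 fell in the mutant (2 and 1 adjusted over the list alone), Rhox6 being at -0.81 from the processed signals and the deposited value table. Of the immediate early genes 2 rose and 2 fell, and 3 rose and 2 fell (2 and 2, and 5 and 3, adjusted over the list alone). Of the sex-linked markers 0 changed in the wild type, and Xist rose and Eif2s3y and Ddx3y fell in the mutant (2 risen, 3 fallen adjusted over the list alone). In the embryo lists 0 of 7 neural and 0 of 4 somite, limb and allantois markers changed in either genotype, also 0 adjusted over the list alone. Median, mean and camera direction were not all of 1 sign for the decidua (median -0.05, mean 0.08) and sex-linked markers (median 0.03, mean -0.26) in the wild type. In the mutant they differed for the heat shock genes (median -0.02, mean 0.10), globins (median -0.05, mean 0.05) and sex-linked markers (median -0.13, mean 0.13). There they also differed for early haematopoietic genes (median -0.007, mean 0.03), endothelial genes (median 0.007, mean -0.02) and trophoblast markers (mean 0.05, camera direction down).

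**Figure D4:**
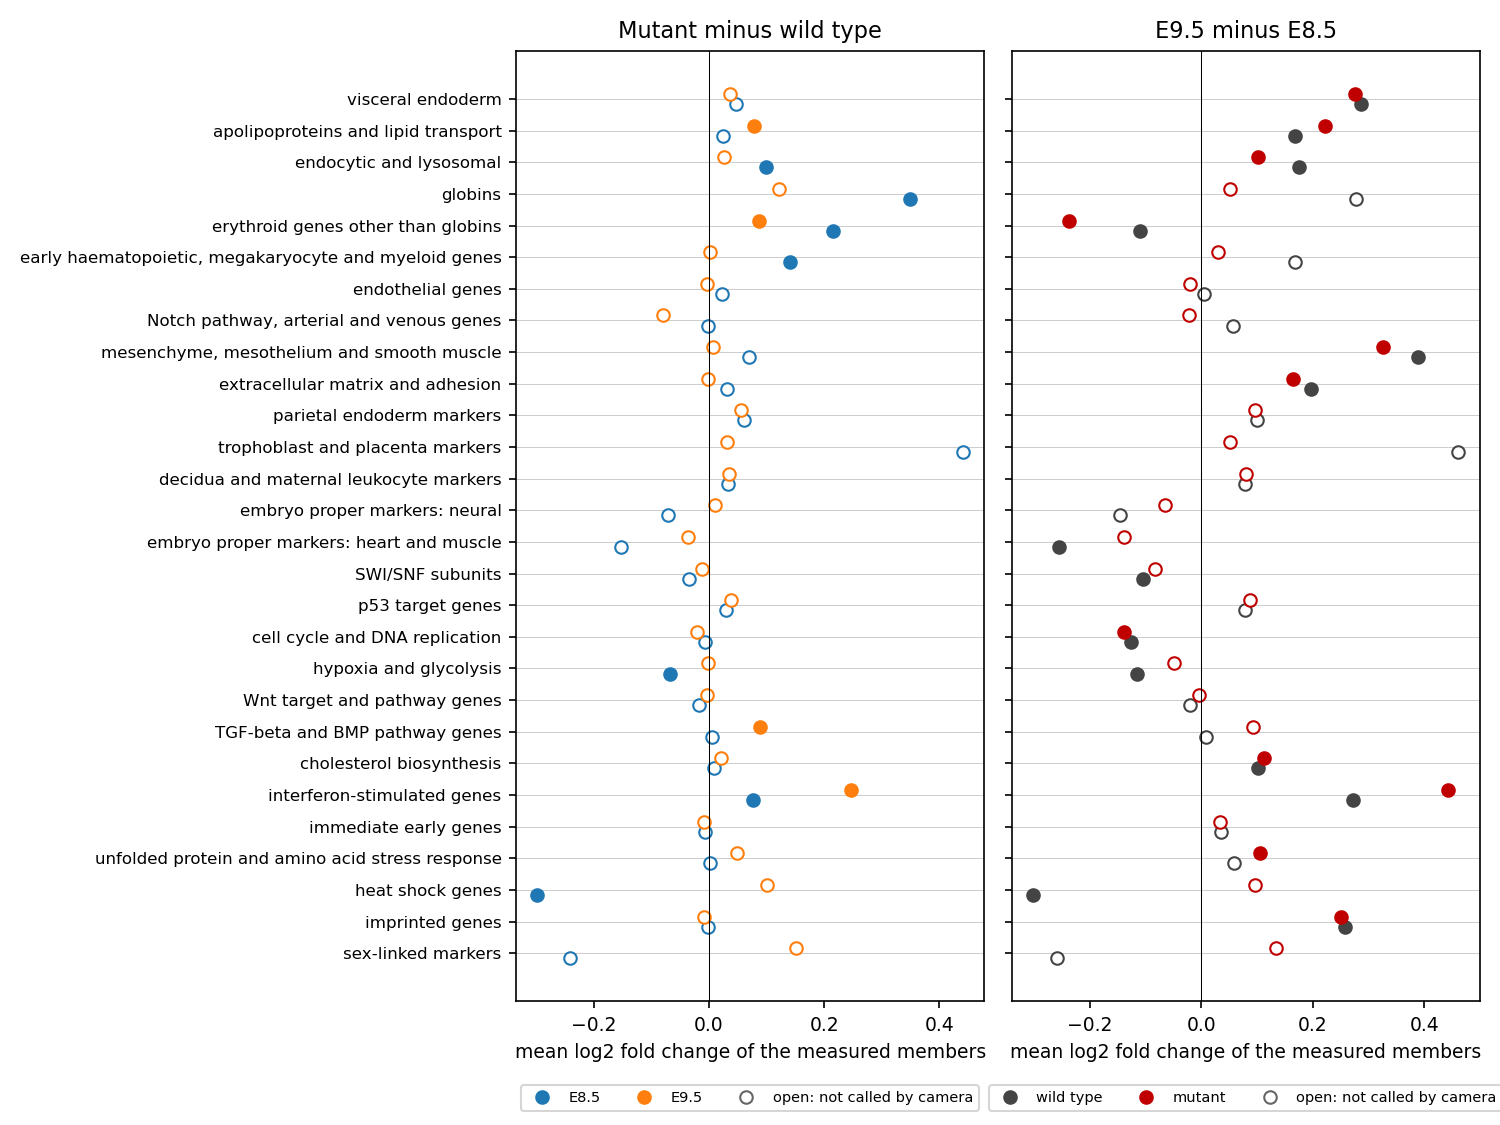
The horizontal axis gives the mean log2 fold change of the measured members of each gene list for mutant minus wild type at E8.5 and E9.5 (left) and for E9.5 minus E8.5 in wild type and mutant (right); filled symbols mark lists called by camera with its preset correlation. Of the filled symbols, only the interferon-stimulated genes at E9.5 (0.25) were also called with an estimated correlation.

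In total 3303 genes changed with stage in the wild type, 1786 up and 1517 down, and 3003 in the mutant, 1526 up and 1477 down. Of these 54 and 50 changed at least 2-fold. The sign was the same on the 3 slides for 3288 and 2967 of them, and with the slide as a block the counts were 3925 and 3473. At an unadjusted p under 0.05 there were 4962 and 4613 genes, and the groups did not overlap in 5201 and 5344, where chance gives 10%. Both genotypes shared 2064 calls, 1122 up and 937 down in both (196 and 161 for independent calls) and 5 in opposite directions. Across all genes the stage effects correlated with Pearson's r = 0.805 and Spearman's rho = 0.752, and 96% of the 4242 genes called in either genotype had the same sign. Camera called 14 lists in the wild type and 11 in the mutant, 0 of them with an estimated correlation, and fry 15 and 10. Median centring moved the median of all genes by 0.106 in the wild type and 0.142 in the mutant and gave 1458 genes (1381 up) and 1755 (1677 up). The Xist covariate gave 1389 in the mutant. Of 111 and 105 named genes called, 12 and 13 lost their call without at least 1 array, among them Hba-a1, Xist (1.75 to 2.96) and Hspa1a (1.19 to 1.91).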

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

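The test on decidua and maternal leukocyte markers was chosen after the result it measures was seen, and the Xist level as a covariate was added after the data were seen; the other tests in this part were planned.

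Camera called 7 gene lists for a difference between the mutant effects at E8.5 and E9.5, and each is given here because of that call. The globins (interaction -0.227; mutant effect 0.349 at E8.5 and 0.122 at E9.5; camera adjusted p = 0.042; adjusted p = 0.812 with an estimated correlation) were lower on 2 of 3 slides. The other erythroid genes (interaction -0.127; 0.215 and 0.087; camera adjusted p = 0.0096; adjusted p = 0.87 with an estimated correlation) were also lower on 2 of 3 slides. The early haematopoietic, megakaryocyte and myeloid genes (interaction -0.139; 0.14 and 0.001; camera adjusted p = 0.00109; adjusted p = 0.719 with an estimated correlation) were lower on 3 of 3 slides. The hypoxia and glycolysis genes (interaction 0.066; -0.067 and -0.001; camera adjusted p = 0.0239; adjusted p = 0.87 with an estimated correlation) were higher on 2 of 3 slides. The TGF-beta and BMP genes (interaction 0.083; 0.005 and 0.089; camera adjusted p = 0.0133; adjusted p = 0.719 with an estimated correlation) were higher on 3 of 3. The heat shock genes (interaction 0.398; -0.298 and 0.101; camera adjusted p = 1.34e-06; adjusted p = 0.14 with an estimated correlation) were higher on 3 of 3 slides. The interferon-stimulated genes (interaction 0.171; 0.076 and 0.247; camera adjusted p = 1.07e-07; adjusted p = 0.14 with an estimated correlation) were also higher on 3 of 3. Among the arrays, the heat shock level was highest in wild-type E8.5 replicates 1 and 3.

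Of 100 splits of the 12 arrays that kept the stages, drawn with a fixed seed, 28 gave as many called lists as the real 7. The highest other gave 12. These splits did not keep the arrays of a slide together, so the number of lists is neither set apart from chance by them nor shown to be chance. For single genes limma's real count was 0, which no split can fall below, so its comparison with the 100 splits decides nothing. The highest other called 649 genes. That split exchanged mutant and wild type at 1 stage, which adds the mutant effects of the stages in place of subtracting them, so the structure of the samples behind it is the effect shared by both stages. The next highest called 40.

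The interferon-stimulated genes were 0.247 higher in the mutant at E9.5, with 14 of 23 genes higher on all 3 slides, and the highest other of the 10 splits of these 6 arrays, too few for a share under 0.05, gave 0.147. Later developmental timing of the mutant is argued against, since the slope of the mutant effect on the stage effect gave the list a shift of -0.014 against measured slide shifts of 0.15, 0.264 and 0.326. Maternal tissue is argued against as the whole source by the mean of 12 decidua and maternal leukocyte markers, 0.034 (standard error over genes 0.043). The sex make-up is argued against by the shift of 0.254 that was left with the Xist level as a covariate (camera adjusted p = 8.99e-15; 1.06e-19 to 0.0484 over 21 alternatives, with the list higher on 3 of 3 slides). What also stays open, untested, is an effect of the mutation on interferon signalling, strain variation carried along with the mutated allele, and the position on the slide, which cannot be told apart from genotype.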

How the results depend on the processing

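The speck, offset 10, Xist covariate, fit without the 4 arrays, block within genotype and slide block for lists were chosen after seeing the data. Of the values recorded for the named genes, 539 of 760 at E8.5, 621 of 719 at E9.5, 2003 of 2106 with stage in the wild type and 1889 of 1993 in the mutant kept their direction and their side of the threshold. For the called lists these were 117 of 147, 63 of 84, 99 of 147 (interaction), 247 of 294 and 208 of 231. Gene counts at E8.5 lay between 161 and 229 without background subtraction, with processed signals, Cy5 alone, scale normalization, both other filters, both other probe rules, the deposited value table, a trended robust prior or the offset of 10.

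Where a result moved by over 1.5 times or crossed its threshold, the cause was not tested, except that stricter and looser thresholds change counts by construction, and fits of fewer arrays have less power. Genes changed at E8.5 (201) were 10 with median centring, 123 from the 2 groups alone, 423 with array weights, 11 with the speck left in, 25 with the Xist covariate, 6 at a log2 change of at least 1, 388 at an adjusted p under 0.1. Leaving out 1 array gave 91 to 221. Those at E9.5 (274) were 170 with processed signals, 26 with median centring, 181 from the deposited value table, 43 with the speck, 134 with Xist, 2 at the fold limit and 465 at 0.1. Leaving out 1 array gave 145 to 369. Limma's interaction count (0; 800 genes at an unadjusted p under 0.05) was 1 without background subtraction, with Cy5 alone, with the slide as a block or with a trended robust prior, 4 with the replicate block, 5 with array weights, 12 without the 4 arrays, and 0 to 5 leaving out 1 array. With stage, the wild type (3303) gave 1458 with median centring, 927 with the speck, 54 at the fold limit and 2288 to 3308 leaving out 1 array. The mutant (3003) gave 1755, 1173, 50 and 2132 to 3365, with 1389 under Xist and 1814 without the 4 arrays. Median centring moved the median of all genes by -0.089 at E8.5, -0.056 at E9.5, 0.106 and 0.142 with stage. With the mean of its group subtracted from each array, correlations were taken between arrays of different groups. Averaged over the arrays of a slide, they were highest for all 12 arrays with their own replicate number, which is also the slide. Within the same number they were 0.176 to 0.381 between stages of 1 genotype and 0.0784 to 0.301 between mutant and wild type of 1 stage. Since 1 of these, at E8.5, lay under 0.1, the numbers were not taken as pairs. Those of mutant and wild type at E9.5 were 0.137, 0.295 and 0.144, so the main fit and the splits leave out a likeness between arrays of a slide. With the slide as a block limma called more genes in every contrast. With the replicate as a block the counts were 268, 327 and 4, and within each genotype 3908 and 3511. The slide as a block added the trophoblast and heart lists at E8.5 and in the interaction and lost the erythroid list with stage in the wild type; it changed no other list call. That block within each stage cannot be fitted for the stage contrasts.

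The correlation of stage effects (0.805) was 0.717 with processed signals, 0.759 without a filter and 0.758 (without mutant E9.5 replicate 3) to 0.808; that of the mutant effects (0.396) ranged from 0.32 to 0.427. Arid1a with stage was -0.153 (adjusted p = 0.393) in the wild type with median centring and -0.36 to -0.279 leaving out 1 array. In the mutant it was -0.195 (adjusted p = 0.055) without background subtraction, 0.004 (adjusted p = 0.982) with median centring, and -0.259 to -0.163. Called lists numbered 0, 1, 0, 0 and 0 in the 5 contrasts with an estimated correlation, against 7, 4, 7, 14 and 11. Fry gave 1, 1 and 0 for the first 3. The Xist covariate gave 3 at E8.5, and processed signals 1 at E9.5 and 2 for the interaction. Leaving out 1 array gave 5 to 8, 1 to 4 (1 without wild-type E9.5 replicate 1, 2 without replicate 3), 4 to 9 (4 without mutant E9.5 replicate 2), 10 to 14 and 10 to 11. Reversed were Rhox6 with stage in the wild type (-0.814 with processed signals and the deposited values), Hspe1 with stage in the mutant (0.031, median centring), the erythroid list at E9.5 (-0.04 without mutant E9.5 replicate 1; 0.179 without replicate 3), the globin and erythroid interactions with the Xist covariate (0.133 and 0.133, the erythroid list being called in that direction and the globins not), and the erythroid interaction without the 4 arrays (0.032, not called). Without the 4 arrays camera also lost the endocytic (0.062) and hypoxia (-0.019) calls at E8.5, the apolipoprotein call (0.044) at E9.5, and the globin (-0.111) and TGF-beta (0.062) calls of the interaction. With stage it lost the apolipoprotein (0.15), heart (-0.102), SWI/SNF (-0.051) and cholesterol (0.1) calls in the wild type and the endocytic (0.05) and erythroid (-0.114) calls in the mutant. The mean of the kept probes ended the erythroid call at E9.5 (0.078). With stage, the replicate block within each genotype ended the erythroid call in the wild type (-0.11) and the endocytic call in the mutant (0.102). The signal limits these results for dim genes: about 50% of the probes were above background, and the median Cy5 signal of 43.1 to 46.8 stood little over the local background of 35 to 37.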

Other observations

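The tests of the neighbours of Arid1a on chromosome 4 were chosen after the results were seen, apart from that of other probes among the nearest 50 genes; the tests of developmental timing and of other splits were planned.

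Several genes called in the mutant lie near Arid1a on chromosome 4, among them Rpl11 (-0.81 at E8.5 and -0.88 at E9.5), Pafah2 (-0.59 and -0.68) and Snhg3 (-0.47 and -0.46). The first test, of the 50 tested genes nearest to Arid1a, held too few called genes to decide: 3 were called at either stage (6%, against 2.96% of other genes), 19.7% of 11188 other windows held as many, genes of the same brightness elsewhere gave 1.41, and 0 of the 3 had other probes. Of windows of 10, 25, 50 and 100 genes on each side, with 0, 3, 10 and 18 called genes, the widest was chosen after these counts were seen: there 0 of 7957 other windows held as many as its 18 (highest 12, 95th percentile 11), and brightness, which gave 5.62, is argued against. Of its 5 called genes with several probes, 0 had another probe moving the same way by at least 50% as much at the stage with the smaller p. At E8.5, where Eloa was not called, 1 of its other probes did (0.18 beside 0.23). The remaining probe of Eloa moved the opposite way, by -0.20 ± 0.06 at E8.5 and -0.40 ± 0.06 at E9.5 (beside 0.32). In 4 of the 5 the other probes were dimmer than the median gene (mean log2 intensity 5.91 to 7.05, against 7.44). There a change is compressed, which does not account for the opposite sign in Eloa. That leaves Rcc2 (9.54) and the opposite probe of Eloa, too few to decide. Sequence differences under single probes stay open, as do, untested, expression differences of the strain that carried the mutation and an effect of the mutated protein.

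The mutant effect was set against the change from E8.5 to E9.5 to ask whether the mutant was early or late in development. At E8.5 the slopes on the 3 slides were -0.02, 0.069 and -0.029, with a mean of 0.007 and a standard error of 0.031. Each slope lay within 0.1 of 0, but a standard error from 3 slopes is too uncertain to exclude a shift in timing of 0.1 of the stage effect. At E9.5 the slopes were -0.161, -0.033 and 0.093, with a mean of -0.033 and a standard error of 0.073. Here a shift of 0.1 in either direction stays open as well, because the slides differ by more than that. The genes that rose with stage in both genotypes, 1122, had median mutant effects of 0 at E8.5 and -0.011 at E9.5, and the 937 that fell had 0.001 and -0.007.

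Each comparison of 3 arrays with 3 allows 10 splits, too few for a share under 0.05, and these splits did not keep the arrays of a slide together. Limma's real count of 201 genes at E8.5 was met by 1 split, the real one, the highest other giving 6. The real 274 at E9.5, 3303 with stage in the wild type and 3003 in the mutant were each met by 1, the real one, the highest other giving 0. For lists called by camera, 3 splits gave at least the real 7 at E8.5 (highest other 8) and 9 the real 4 at E9.5 (highest other 11). With stage, 2 gave the real 14 in the wild type (highest other 15), and 1 the real 11 in the mutant (highest other 8). At E8.5 and E9.5, then, the number of lists called with the preset correlation is not set apart from other splits.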
